A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

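RNA from 6 yeast cultures was measured on the Affymetrix Yeast Genome 2.0 array, 3 with the empty vector pYES3 and 3 with pYES3 carrying GmbHLHm1, all in strain 26972c. Per the labels, total RNA was extracted with hot acid phenol after 12 h in medium with 2% galactose and 0.5 mM ammonium sulfate. The deposited values are intensities on a linear scale, made by the authors with RMA (background correction, quantile normalization and a summary over the probes of a set), per the submitters' processing notes; the software and its version are not given in the sources used here. That the scale is linear was read from the values, which run from 5.00 to 28314. RMA makes the arrays' overall distributions alike, so a change of all transcripts together would not be seen. The log2 of each value was taken here.

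The table holds 10928 probe sets. The platform annotation pairs 7245 of these with genes, 7244 with 1 gene symbol and 1 with several, and the remaining probe sets are unnamed here. A total of 5498 probe sets had a gene identifier of S. cerevisiae in the gene table of assembly R64, which was used for names and neighbours only, and 12 symbols were updated through it. Of the 5449 genes 47 had more than 1 probe set; the one with the highest mean over the 6 arrays stood for the gene. For TPO2 the probe set used had a log2 change of 0.07 and the other 0.84. Another 1746 probe sets had gene identifiers outside that table. The array also carries probe sets for fission yeast; the annotation does not state the species, and these 1746 were taken as probe sets without an intended target in this sample. Their 95th percentile on an array served as its background level. The 3517 unnamed and 166 control probe sets were not tested with the genes. TRP1 and GAL4, of the fixed lists, are not named by the annotation used here.

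Groups were taken from the labels. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no filter on dim probe sets, no block, two-sided), with Benjamini-Hochberg adjustment over the 5449 genes and a threshold of 0.05. A 2-fold floor was counted separately. Gene lists with at least 3 tested members and the 16 chromosomes were tested with camera at a preset correlation of 0.01, and the lists also with camera at an estimated correlation and with fry. Standard errors are the moderated ones. The steps were tested on simulated data of 5449 genes and 3 arrays per group in 5 draws with 200 changed genes each. At a log2 size of 0.5 the fit recovered 91.9% of the changed genes and at 1 and 2 it recovered 100%, and 44 of 26245 unchanged genes were called. The simulated noise was independent between genes and had the same SD in both groups, unlike these data, so these rates may not carry over. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

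The tests, the lists, the alternatives and the rule for named genes were written before the data were examined, except where the text says otherwise. The rule names the 12 highest and 12 lowest log2 changes among genes past the test whose groups do not overlap. It always names the genes touched by the strain or construct, AMF1, PHO84 and the bHLH genes of yeast. For each list described, the rule names up to 2 of the highest and 2 of the lowest members past the test. Where none passes, it names the member with the smallest p. AMF1 and PHO84 were put in the rule by name, and whether earlier reports on these arrays shaped that choice is not recorded. The alternatives were a replicate block, quantile normalization or median centring of the tested probe sets, a filter on dim probe sets, array weights, a trend and robust prior, no moderation, all probe sets, the mean over probe sets, a stricter threshold, and leaving out each array.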

Results

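Transcript levels were measured on 6 arrays in the budding yeast strain 26972c, which carries a mutated MEP1 gene and a deleted MEP2 gene and takes up ammonium poorly. On 3 arrays the cells held the empty expression vector pYES3, and on 3 they held pYES3 with GmbHLHm1, a soybean gene for a basic helix-loop-helix (bHLH) transcription factor also named SAT1, under a promoter that galactose switches on. All cultures were sampled after 12 h with 2% galactose and 1 mM ammonium. The comparison asks which yeast genes differ in transcript level between cells with the soybean gene and cells with the empty vector. A total of 5449 genes was tested, 1 probe set per gene. Values are log2 RMA intensities, and their median over the tested genes lay between 10.32 and 10.37 on the 6 arrays. Between 98.3% and 98.9% of the tested genes lay above the array's background level, which was 23.2 to 26.9 in intensity. Arrays of the empty vector group correlated with each other across genes at r = 0.9986 to 0.9987, those of the GmbHLHm1 group at 0.9938 to 0.9963, and arrays of different groups at 0.987 to 0.989. Genes are not independent replicates in these correlations. The median SD within a group was 0.0502 log2 units for the empty vector and 0.0875 for GmbHLHm1. The number of arrays, 3 per group, limits the precision. The labels call the replicates independent, but the cultures were started from shared starter cultures, so the p-values measure only the spread between these samples. If a starter was shared only within a group, a difference between starters or transformants cannot be told apart from an effect of GmbHLHm1.

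The genes that the strain and the construct touch were examined first. The deleted MEP2, a high-affinity ammonium permease gene, lay below the background level on all 6 arrays, so no fold is given for it. MEP1, the permease gene that is mutated in this strain, fell by 0.46 ± 0.08 (SE) on the log2 scale in GmbHLHm1 cells (adjusted p = 0.0109). MEP3, the third ammonium permease gene, rose by 0.91 ± 0.16 (SE; adjusted p = 0.0138). URA3, an enzyme gene of pyrimidine synthesis often used as a selection marker, rose by 1.35 ± 0.22 (SE; adjusted p = 0.0105), from 9.88 ± 0.28 to 11.23 ± 0.42 (SD, n = 3 per group). These calls lie near the threshold. Without empty vector replicate 1 the adjusted p of URA3 was 0.0533, without empty vector replicate 3 that of MEP1 was 0.052, and without empty vector replicate 1 or 2 that of MEP3 was up to 0.0677. The soybean gene itself has no named probe set here, so its transcript was not measured.

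The largest rise in GmbHLHm1 cells was that of AMF1 (YOR378W), a membrane transporter of the major facilitator family, which went from 5.93 ± 0.05 to 11.75 ± 0.24 (SD, n = 3 per group), a fold of 56.5. PHO84, the high-affinity phosphate transporter gene, followed with a fold of 38.7, from 8.45 ± 0.10 to 13.72 ± 0.02. BAP3, an amino acid permease gene, rose 17.6-fold, RIM4, a gene for an RNA-binding protein of meiosis, 14.8-fold, and PHM6, a gene of the phosphate response, 13.4-fold. The next highest were PRY2, PUN1, GIT1, DAN1, PSA1, YGL041C-B and MNN1, with log2 changes between 2.49 for PRY2 and 2.22 for MNN1. GIT1 encodes a transporter of glycerophosphoinositol, PSA1 the enzyme that makes GDP-mannose, MNN1 a mannosyltransferase, and DAN1 a cell wall mannoprotein. All 12 kept an adjusted p under 0.05 in each of the 6 fits that left out 1 array.

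Decreases were smaller. The lowest gene was DAL4, the allantoin permease gene, which fell by 1.45 ± 0.13 (SE) on the log2 scale, from 10.83 ± 0.07 to 9.38 ± 0.29 (SD, n = 3 per group). It was followed by YOR387C, which fell by 1.41, and HXT11, a hexose transporter gene, which fell by 1.36. VEL1 fell by 1.14 (adjusted p = 0.0138, and 0.052 without empty vector replicate 3), and the membrane protein gene MRH1 by 1.14. FLO11, a cell surface flocculin gene, fell by 1.05, and SUC2, the invertase gene, by 1.02. TPO3, a polyamine exporter gene, fell by 0.92, HXT4 by 0.90, SEO1 by 0.86, IRC15 by 0.83 and DLD3 by 0.83.

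**Figure D1:**
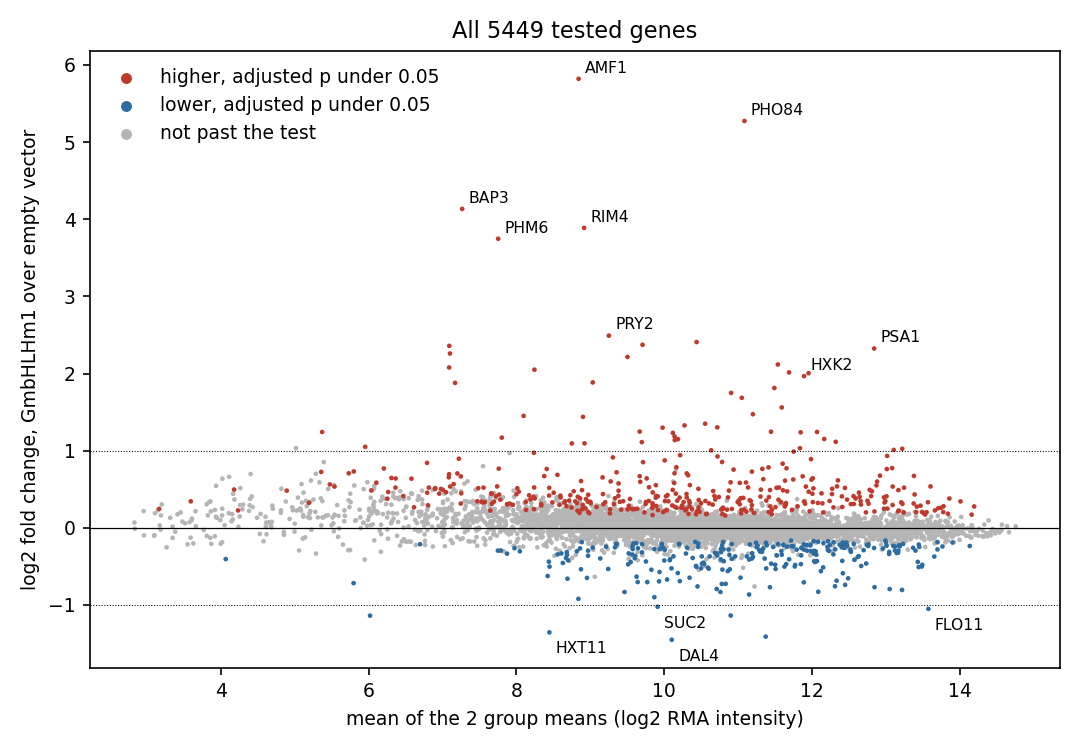
Each point is 1 of the 5449 tested genes, with the mean of the 2 group means (log2 RMA intensity) on the x axis and the log2 fold change of GmbHLHm1 over empty vector on the y axis. Red points are higher and blue points lower at an adjusted p under 0.05, dotted lines mark 2-fold, and AMF1 at 5.82 and PHO84 at 5.27 stand at the top.

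In all, 659 genes changed, 406 higher and 253 lower, and 58 of these changed at least 2-fold, 51 higher and 7 lower. Of the genes, 17 were at least 4-fold higher and 5 at least 8-fold higher. In all 659 the values of the groups did not overlap, which passing this test with 3 arrays per group nearly requires, so it is no separate support. Over all tested genes 33.2% had groups that did not overlap, where chance gives 10%. The median log2 change over the tested genes was 0.02. The test was limma's moderated test, two-sided, with Benjamini-Hochberg adjustment. Without empty vector replicate 1, 2 or 3 the 659 became 251, 341 and 293, without GmbHLHm1 replicate 1, 2 or 3 they became 723, 720 and 462, and without moderation 284 genes passed; the count of 2-fold changes stayed between 53 and 62 without any 1 array. The fit took 1 variance per gene for both groups, although the SD within the GmbHLHm1 group was larger. Array weights were 1.486, 1.643 and 1.841 for empty vector replicates 1, 2 and 3, and 0.347, 0.512 and 1.25 for GmbHLHm1. The count rose without GmbHLHm1 replicate 1 or 2, the arrays of lowest weight, and fell without any other array. Without GmbHLHm1 replicate 1 or 2, 564 and 539 of the 659 kept the call. The excess of higher over lower genes depends on the scaling, since quantile normalization of the tested genes gave 331 higher and 332 lower.

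**Figure D2:**
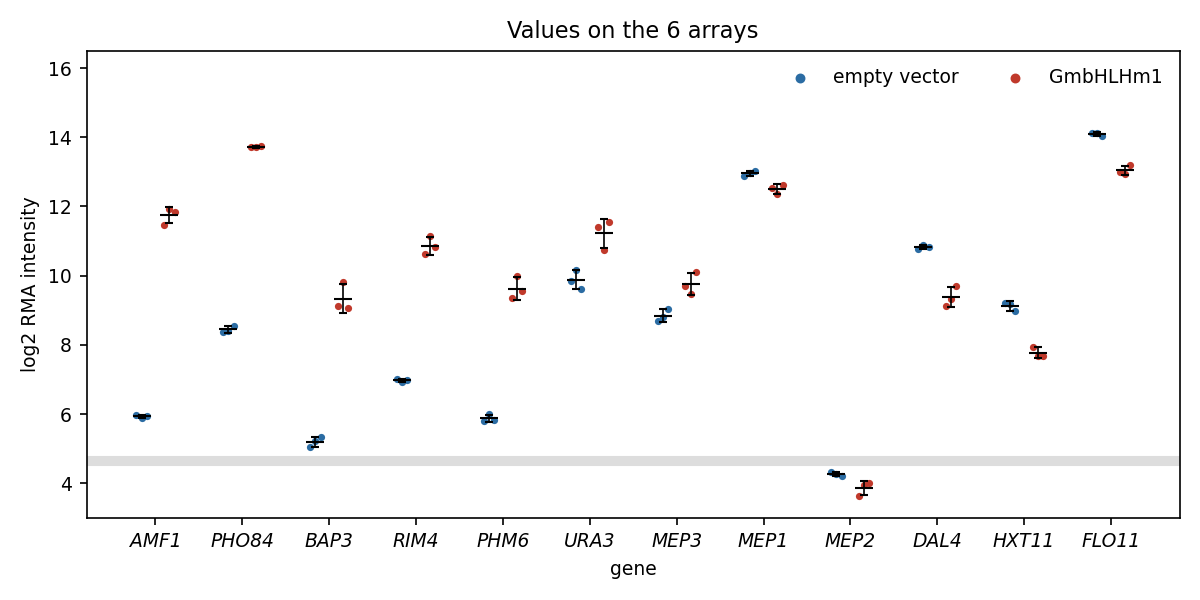
Points are the log2 RMA intensities of 12 genes on the 3 empty vector arrays (blue) and the 3 GmbHLHm1 arrays (red), with the mean and SD of each group in black. The grey band spans the background level of the 6 arrays; MEP2 lies below it in both groups, while AMF1 goes from 5.93 to 11.75.

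The genes were then grouped into 43 lists fixed before the data were examined, and 17 lists shifted against the other genes with camera at a preset correlation of 0.01, 5 upward and 12 downward. With an estimated correlation none of the 43 passed. That setting also takes its degrees of freedom from the 6 arrays and not from the number of genes. It therefore has little power here, and a list that fails it is not shown to be unshifted. Other groupings of the 6 arrays into 3 and 3 gave up to 22 lists at the preset correlation. Those groupings mix both groups on each side and keep part of their difference, so they do not show what no difference would give. Since the calls depend on the setting of camera, the counts of genes within each list are given below. Genes that move together also raise such counts. Over all 5449 tested genes 12.1% changed, 406 higher and 253 lower. The counts for mitochondrial ribosomal proteins, environmental stress and autophagy do not stand out from this share. On the same GmbHLHm1 arrays the control probe sets for 18S and 25S ribosomal RNA were lower, by a median log2 change of -1.01 over 16 probe sets, 13 of them without overlap between groups. The mean over these probe sets differed by -1.14 between the groups (SD between arrays 0.33 for the empty vector and 0.24 for GmbHLHm1, n = 3 per group; exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows). The probe set for 5.8S ribosomal RNA overlapped between the groups, with a log2 change of -0.09.

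Of 21 tested genes of the phosphate response that the yeast bHLH factor Pho4 drives, 13 rose and none fell (16 rose when adjusted over the list alone), with a median log2 change of 0.87. The highest were PHO84, PHM6 and GIT1, with log2 changes of 5.27, 3.75 and 2.37. PHO4 itself had a log2 change of 0.11 ± 0.06 (SE; adjusted p = 0.268). The list passed camera (adjusted p = 1.19e-14), with adjusted p = 0.175 with an estimated correlation. Among the 8 bHLH factors of yeast, HMS1 rose by 1.10 and TYE7 by 0.52, and the other 6, PHO4, CBF1, INO2, INO4, RTG1 and RTG3, did not pass the test. The bHLH list as a whole did not pass camera (adjusted p = 0.144). It passed fry, upward, which tests a list against no change and not against the other genes (adjusted p = 0.000159).

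Of 36 tested genes for the respiratory chain and ATP synthase, 25 rose and none fell (31 rose when adjusted over the list alone), with a median log2 change of 0.28. ATP17, a subunit of ATP synthase, rose by 0.60 and CYC1, cytochrome c, by 0.55. The adjusted p was 4.58e-16 with camera and adjusted p = 0.134 with an estimated correlation. Of 55 mitochondrial ribosomal protein genes 4 rose and none fell (3 rose when adjusted over the list alone), and the list had a median of 0.09, with adjusted p = 0.00292 with camera and adjusted p = 0.711 with an estimated correlation. None of the 128 genes for cytosolic ribosomal proteins passed limma's test over all genes, and of 50 ribosome biogenesis genes 1, TIF6, fell (none when adjusted over the list alone); TIF6 did not pass without any 1 empty vector array, with an adjusted p of up to 0.105. Neither of these lists passed camera (adjusted p = 0.39 and 0.794), while the 18S and 25S ribosomal RNA probe sets were lower on the same arrays.

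Part of the genes for nitrogen use, amino acid permeases and sulfur and methionine metabolism fell. Of 31 targets of nitrogen catabolite repression 13 fell and 1 rose (14 and 1 when adjusted over the list alone), with a median log2 change of -0.22. DAL4 fell by 1.45 and UGA4, a permease gene for gamma-aminobutyrate, by 0.76, and the 13 include MEP2, which lay below background in both groups. The list passed camera at adjusted p = 2.73e-06, with adjusted p = 0.367 with an estimated correlation. Of 23 amino acid permease genes 11 fell and 1 rose (15 and 2 when adjusted over the list alone). MMP1, an S-methylmethionine permease gene, fell by 0.71, whereas BAP3 rose by 4.13 ± 0.19 (SE). This list gave adjusted p = 2.31e-05 with camera and adjusted p = 0.367 with an estimated correlation. Of 27 sulfur and methionine genes 14 fell and 1 rose (18 and 1 when adjusted over the list alone), with a median of -0.33. The sulfate permease gene SUL2 fell by 0.79, MMP1 by 0.71, and STR3, a cystathionine beta-lyase gene, rose by 0.58. Its adjusted p was 4.8e-10 with camera and adjusted p = 0.367 with an estimated correlation. The nitrogen and permease lists share 5 members and the permease and sulfur lists 4, so they are not independent.

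Of the 5 genes for ammonium assimilation 2 fell (2 when adjusted over the list alone), GDH3, a glutamate dehydrogenase gene, by 0.44 and GLT1, the glutamate synthase gene, by 0.24. The adjusted p of this list was 0.0314 with camera and adjusted p = 0.367 with an estimated correlation, and without GmbHLHm1 replicate 1 or 2 it was 0.0785 or 0.145. GLT1 alone did not pass without any 1 of the 3 empty vector arrays, with an adjusted p of up to 0.0911. Among 8 genes for ammonium and ammonia transport, AMF1 and MEP3 rose. ATR1, MEP1 and MEP2 were past the test in the other direction, MEP2 below background (2 and 3 when adjusted over the list alone). The list as a whole did not pass camera (adjusted p = 0.548). AMF1 was placed in this list by name. If earlier reports on these arrays shaped that choice, the rise of AMF1 there is no independent result. ATR1, a multidrug transporter gene, fell by 0.51 and lost its call without any 1 empty vector array or without GmbHLHm1 replicate 3, with an adjusted p of up to 0.133.

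Further lists past camera, for transport and other functions, held more members that fell than rose. Of 21 genes for polyamine, urea, allantoin and nucleobase transport 8 fell and 2 rose (11 and 2 when adjusted over the list alone). DAL4 fell by 1.45 and TPO3 by 0.92, and THI7, a thiamine transporter gene, rose by 0.78; the adjusted p was 0.000167 with camera and adjusted p = 0.367 with an estimated correlation. Of 25 multidrug resistance genes 9 fell and 3 rose (12 and 3 when adjusted over the list alone). HXT11 fell by 1.36, and PDR16, a lipid transfer protein gene, rose by 0.53. The adjusted p was 0.000458 with camera and adjusted p = 0.175 with an estimated correlation. The polyamine list shares 3 members with the nitrogen list and 4 with the multidrug list, so these are not independent. Of 15 zinc regulon genes 6 fell and 1 rose (8 and 1 when adjusted over the list alone), with ZRT2, a low-affinity zinc transporter gene, down by a log2 change of -0.35; the adjusted p was 5.2e-05 with camera and adjusted p = 0.281 with an estimated correlation. Of 18 genes for gluconeogenesis and the glyoxylate cycle 6 fell and 2 rose (7 and 2 when adjusted over the list alone). The carnitine acetyltransferase genes YAT1 and YAT2 fell by 0.79 and 0.69, and ADR1, a transcription factor gene of this response, rose by 0.51; the adjusted p was 0.00269 with camera and adjusted p = 0.367 with an estimated correlation.

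Of 24 genes that are switched on at the start of the cell cycle 5 rose and none fell (10 rose when adjusted over the list alone). MNN1 rose by 2.22 and the G1 cyclin gene CLN2 by 0.65, the latter past the test only with all 3 empty vector arrays and GmbHLHm1 replicate 3, with an adjusted p of up to 0.16 otherwise. The list gave adjusted p = 0.000185 with camera and adjusted p = 0.367 with an estimated correlation. Of 24 mating genes, included as markers of mating type, 8 rose and none fell (9 rose and 2 fell when adjusted over the list alone). MFA2, an a-factor gene, rose by 1.33, and MF(ALPHA)1, an alpha-factor gene, had a log2 change of 0.64 and an adjusted p of 0.0203, or up to 0.093 without empty vector replicate 1 or 2. The list gave adjusted p = 0.00705 with camera, adjusted p = 0.367 with an estimated correlation, and 0.0592 without GmbHLHm1 replicate 2. Of 30 genes of meiosis and sporulation 1 rose and 1 fell (none and 1 when adjusted over the list alone), and the list did not pass camera (adjusted p = 0.417).

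Of 12 tested genes of the galactose regulon, which serve growth on the sugar used here, 1, FUR4, fell and none rose (the same counts when adjusted over the list alone), with a median log2 change of 0.02 and adjusted p = 0.972 with camera. FUR4 fell by 0.28 and passed only in the fit with all 6 arrays and in that without GmbHLHm1 replicate 2. In the list of glycolysis and fermentation genes 3 rose and 1 fell of 19 (3 and 1 when adjusted over the list alone), with HXK2, the hexokinase 2 gene, up by 1.97 ± 0.08 (SE). That list did not pass camera (adjusted p = 0.934). The other lists past camera, with medians between -0.10 and -0.05, were those for Gcn4 amino acid synthesis, oxidative stress, environmental stress and autophagy, in which 6, 3, 3 and 3 members fell and 3, 1, 3 and 1 rose, of 42, 23, 42 and 26 (12, 3, 6 and 3 fell and 4, 1, 3 and 1 rose when adjusted over the list alone). With camera their adjusted p values were 0.00278, 0.0045, 0.0215 and 0.0406, and with an estimated correlation 0.667, 0.506, 0.579 and 0.633. The environmental stress list did not pass without empty vector replicate 1 (0.0541), nor the autophagy list without empty vector replicate 1 or 2 or GmbHLHm1 replicate 1 or 3 (up to 0.153). No chromosome shifted as a whole: none of the 16 passed camera, and the smallest unadjusted p was 0.0781, for chromosome IX. Of the 1746 background probe sets 2 passed limma's test when fitted on their own, both lower. At an unadjusted p under 0.05 with limma there were 13.3% of them, a larger share than chance gives at that threshold.

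**Figure D3:**
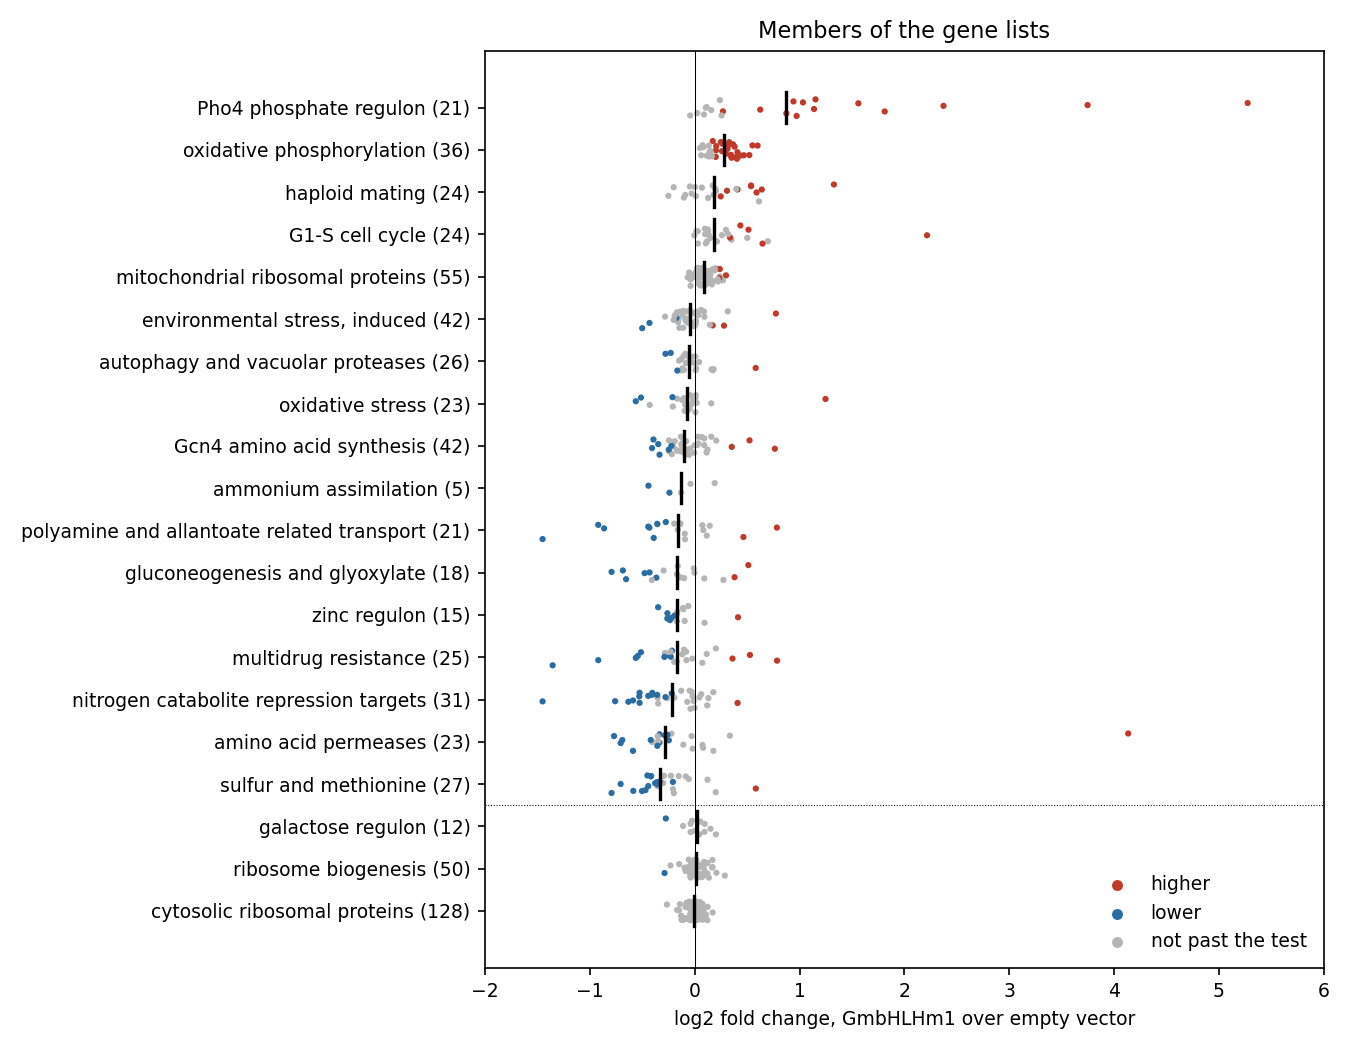
Each point is the log2 fold change of 1 list member, GmbHLHm1 over empty vector, in red if higher, blue if lower and grey if not past limma's test, black bars are list medians, and the number of tested members stands in parentheses. Above the dotted line are the 17 lists past camera at a preset correlation and below it 3 that did not pass; the Pho4 list reaches 5.27 and the respiratory list has its median at 0.28.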

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

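The tests on ribosomal RNA controls, URA3 and the Pho4 list below were chosen after the results were seen, except the slopes within groups, whose prediction did not cover the pairs of arrays. Outside the tested genes, 14 probe sets that the annotation used here does not name changed between the groups (limma, adjusted within the 3517 unnamed probe sets, reporter sequences left out), 8 higher and 6 lower. The largest rise among them was 3.37 on the log2 scale and the next 2.10. Which transcripts they measure was not determined.

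The 16 control probe sets for 18S and 25S ribosomal RNA had a median log2 change of -1.014, for which a different carry-over into the labelled sample and a real difference between the cells, each limited to these species, stay open, untested. Dimmer hybridization of these arrays was predicted to lower the bacterial hybridization controls too, by at least 0.5 of that change, and their median was -0.088 (SD 0.046 over 27 probe sets). Weaker labelling was predicted to lower the labelling controls by as much, and their median was -0.321 (SD 0.125 over 42 probe sets, not arrays). Their means were 7.95, 8.657 and 8.424 on GmbHLHm1 replicates 1, 2 and 3 against 8.611 for the empty vector, so that replicate 1 stood apart. Replicate 2 differed from empty vector replicate 3 by 0.012 in these controls and by -0.907 in ribosomal RNA. However, RMA had already made the arrays' distributions alike, so a dimming or weaker labelling of a whole array would be largely removed from these values. Neither set of controls can therefore decide on it. The same removal acts on the ribosomal RNA values, however. A uniform loss over a whole array would thus not by itself leave a change of -1.014 in them, which argues against it as the only cause. More degraded messenger RNA would shift the difference between the 3' and 5' probe sets of 7 control transcripts, whose median shift was -0.046 (SD 0.103), and a fall of all ribosomal RNA alike would lower the 5.8S probe set, which changed by -0.093 (SE 0.100). If the amount of ribosomal RNA signal set the 659 changed genes, arrays of 1 group with more of it would deviate towards the empty vector profile. The slopes in the 2 groups were 0.134 and 0.004 of the predicted one. Those of array pairs lay between -0.166 and 0.232, except -0.812 for a pair whose ribosomal RNA differed by only 0.063. The 659 genes passed a test that favours a small spread within groups, which itself favours small slopes, so these slopes cannot decide the question.

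The control probe sets for URA3 had a median log2 change of 1.293, beside 1.35 for the URA3 gene. A rise of the whole pyrimidine pathway would lift the 9 other genes of that list, and their median was -0.034 (SD 0.174), with 3 lower and none higher. More copies of the vector or of its transcripts in GmbHLHm1 cells may account for the rise of 1.35 if URA3 is the marker of this vector, which the labels do not state; no probe set is named as vector sequence, so this stays open.

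The higher phosphate genes were weighed because Pho4 is itself a bHLH factor. Cross-hybridization among near-identical acid phosphatases would leave little without PHO5 and PHO11, and the median of the 19 other members was 0.625, with 11 of them past the test. For a rise of the PHO4 transcript a log2 change of at least 0.58 was asked, and it was 0.114, with an upper 95% limit of 0.252. How large a rise the targets would need was not tested, so a smaller rise of PHO4 is not excluded. A binding of GmbHLHm1 to the sites of Pho4, a lower phosphate supply in these cultures and a change in Pho4 activity stay open, untested.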

How the results depend on the processing

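The alternatives of this part were planned, except the count of genes above background, the list without PHO5 and PHO11 and those for the background probe sets, which were chosen after seeing the data. The 659 changed genes became 427 with the replicate block, of which 405 were among the 659, 284 without moderation, 439 over all probe sets, 823 with array weights, 820 with a trend and robust prior, and 120 at an adjusted p under 0.01 and at least 1.5-fold; the last threshold also gives 120 beside the 58 genes changed at least 2-fold. Leaving out empty vector replicate 1, 2 or 3 gave 251, 341 or 293 genes. Leaving out GmbHLHm1 replicate 1, 2 or 3 gave 723, 720 or 462. A link to the spread within groups was not tested. Samples with the same number were not treated as pairs, and their deviations from the group means correlated at -0.065, -0.082 and 0.141. Of the fits under other scalings, quantile normalization gave 663 genes and 49.9% of them higher, median centring 653 and 52.5%, against 61.6% of the 659. Counting only genes above background on all 3 arrays of at least 1 group left 654, and 4 of the 659 were above it on no array. Changes of at least 2-fold numbered 53 to 62 without 1 array. Of the 118 named genes past the test 68 kept the call without any 1 array and 50 lost it at least once, none of the 12 highest and 1 of the 12 lowest, VEL1. With the replicate block 29 lost the call and without moderation 54, 57 kept it under each of up to 14 alternatives run for single genes, which do not include the fit over all probe sets or the stricter threshold, and no named gene reversed in these.

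The 17 lists past camera became 0 with an estimated correlation. The median estimated correlation was 0.136 against the preset 0.01, but a higher correlation does not account for every loss. Multidrug resistance, at an estimated correlation of -0.004, went from an adjusted p of 0.000458 to 0.175 with camera. What else differs between the settings was not tested. The lists past camera numbered 15 to 20 without 1 array and 12 after quantile normalization. Of the 17, 5 lost the call after quantile normalization, 2 with the replicate block, 2 with array weights and 1 with median centring. Fry, which tests a list against no change and not against the other genes, gave 19, with 12 of them among the 17. With fry, 8 lists took the direction opposite to camera, and 2 of these passed fry, ammonium and ammonia transport (median -0.30, fry upward, adjusted p = 0.0087) and glycolysis and fermentation (median -0.0212, upward, adjusted p = 0.0241). Also past fry but not camera, upward in both, were the lists for yeast bHLH factors, cell wall integrity and thiamine and vitamin B6. The same held for anaerobic and cell wall mannoproteins and for potassium, sodium and proton transport. Without PHO5 and PHO11 the Pho4 list still passed camera (median 0.62). No chromosome passed under any alternative run. Of the 1746 background probe sets 2 passed limma's test, both lower (233 at an unadjusted p under 0.05), 1 with the replicate block, 0 with a trend and robust prior and 0 when fitted together with unnamed and control probe sets, the form run first; the cause was not tested. The search for CACGTG sites in promoters was not run, since no genome sequence was used here.

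The 10 splits into 3 and 3 are too few for a share under 0.05. The real split gave 659 genes and the highest other 0, 58 and 0 at the 2-fold floor, and 17 and 22 lists. Counts as high came from 1, 1 and 3 splits. Other splits mix both groups, which raises their spread, so counts of 0 decide nothing.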

Other observations

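The tests of neighbouring genes and of the full tricarboxylic acid cycle were chosen after results were seen, as were the genes named in the next sentences. No enrichment was tested for these genes. EXG1, an exo-1,3-beta-glucanase gene, rose by 2.12 ± 0.10 (SE) on the log2 scale, HPF1, a cell wall mannoprotein gene, by 2.00 ± 0.20, SCW10, a cell wall protein gene, by 1.89 ± 0.17, and GAS1, a glucanosyltransferase gene, by 0.93 ± 0.09. In the fixed list for cell wall integrity 4 of 21 genes rose and 2 fell, and it did not pass camera (adjusted p = 0.182). Without GmbHLHm1 replicate 1 it passed camera (adjusted p = 0.0387), and with all arrays it passed fry, upward (adjusted p = 0.0119). ALD6, the cytosolic aldehyde dehydrogenase gene, rose by 2.01 ± 0.11, GND1, of the pentose phosphate pathway, by 1.69 ± 0.12, and HAP4, which encodes the activating subunit of a regulator of respiratory genes, by 1.25 ± 0.09.

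Since HAP4 and 25 of 36 respiratory genes rose, a Hap4-linked rise may also cover the tricarboxylic acid cycle. A list of 11 cycle genes was drafted, and 4 of these, CIT1, ACO1, IDH1 and IDH2, were set aside before the test because the counts of the Rtg list that holds them had been seen. The other 7 had a median log2 change of 0.234, all 7 positive and 3 past the test (camera p = 8.5e-05, and p = 0.0407 with an estimated correlation), as the hypothesis predicts. With all 11 the median was 0.149, short of the 0.15 that had been asked of the shorter list beforehand, with 3 past the test and all 11 positive (camera p = 0.000197, and p = 0.0256 with an estimated correlation). The result of the shorter list therefore rests in part on which genes were left out, and the hypothesis stays open.

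Neighbouring genes were counted because some of the genes at least 2-fold higher lie side by side. Among the 51 genes there were 2 pairs of immediate neighbours, PHO3 with PHO5 and HSP150 with CIS3, against a median of 0 and a 95th percentile of 2 in 10000 random sets (permutation p = 0.0828). The count did not exceed the 95th percentile. Both pairs are related genes, and cross-hybridization between them was not tested.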
